A study of Mus musculus with 3 samples.

How the data were processed

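RNA was measured in 3 libraries of C2C12 cells, an immortalised mouse myoblast line that fuses into myotubes when differentiated. The libraries came from wild-type cells (WT), from cells labelled as a Drp1 knockout (KO) and from KO cells that transiently expressed FLAG-tagged Drp1 (rescue), all taken 4 days into differentiation. Drp1, the GTPase that divides mitochondria, is the protein of the gene Dnm1l. There was 1 library per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a DNBSEQ-G400RS kit. Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.2.1 and featureCounts 2.0.0, with the mouse build GRCm39 (mm39). The settings of these tools and the strand setting are not given in the sources used here.

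Each deposited table held a raw read count, an RPKM and a TPM per transcript, over 139023 transcript rows of 46316 gene symbols. The deposited count column held whole numbers with no normalization, per the file headers. The RPKM column deposited by the authors was the count per kilobase of transcript, scaled to the total count of the table. The TPM column deposited by the authors was the count per kilobase, scaled to a fixed sum per table. RPKM and TPM recomputed from the counts and lengths differed from the deposited values by at most 4.98e-06 and 4.40e-06, and only the counts were analysed further.

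The counts of different transcripts of a gene were nearly equal. Among 5388 genes with 2 or more mRNA rows and at least 1000 counts in the highest row, the lowest row had a median of 98.0% of the highest. The values therefore look as if a read was counted for each transcript it overlapped, so rows of a gene cannot be added as separate reads. The gene count used was the row with the highest total over the 3 libraries. This choice was made after the tables were seen, and the sum over all rows was an added alternative. Gene counts summed to 13894114 in WT, 13790417 in KO and 13925296 in rescue. How reads matching several genes were treated is not given in the sources used here. Counts of genes with close copies, such as the neighbouring myosin heavy chain genes Myh1, Myh2 and Myh4, and of genes that overlap or lie antisense to another are therefore uncertain.

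Counts were scaled with edgeR 4.0.16 TMM factors in R 4.3.3, which were 1.01 for WT, 1.00 for KO and 0.989 for rescue. The log2 ratio between 2 libraries was taken after adding 0.5 to each count. The 13382 genes with a mean of 1 or more CPM (counts scaled to a common library total) were kept, 11830 of them protein-coding. A gene was counted as higher or lower at a ratio of 2-fold or more. With 1 library per group no difference has a replicate check, and no p-value, SD between replicates or SE was computed. Each ratio has an exact conditional (Clopper-Pearson) 95% counting interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Where 1 library had 0 counts, a fold was computed against 3 counts in that library and is a lower bound.

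Before the data were examined, 32 gene lists with 746 entries, the tests and the rule for named genes were fixed. Listed symbols were matched to the tables directly or through synonyms in a RefSeq table of GRCm38.p6, which was used for names. GC content, used in a test on neighbouring genes, was known for 98.1% of the genes tested there, and neighbours were taken from the order of the deposited tables. The 13 protein genes of mitochondrial DNA were not analysed here. For each other list the median log2 ratio was given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile was computed again with lists matched on transcript length in 5 bins within each expression bin. Such a percentile describes these libraries and is not a test of the conditions. The counting interval of a list median came from 200 Poisson redraws of the counts.

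The rule named 14 genes in advance: Dnm1l, Gdf15, Fgf21, Myh1, Myh2, Myh4, Myh7, Myh3, Myh8, Myog, Myod1, Ppargc1a, Ckm and Acta1. It added the 10 highest and 10 lowest ratios of each pair of libraries among genes with at least 200 counts in the higher library and a named symbol. Symbols made of LOC and a number were left out too, which was decided after the data were seen. It added up to 4 members of each list with the largest ratios of KO against WT and of rescue against KO. It also took the 10 clearest genes that differed 2-fold in KO and 2-fold the opposite way in rescue against KO, and the 10 clearest that stayed 2-fold from WT. The text names only some of the genes selected, and the others are not reported here.

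The comparisons of KO and of rescue with WT share the WT library, and those of KO with WT and of rescue with KO share the KO library. The values that sharing gives with no effect were simulated in 100 draws of Poisson counts at common means, and again with an assumed biological coefficient of variation of 0.1 and 0.2. Alternatives tried were DESeq2 1.42.0 size factors, library totals, no low-count filter, a mean of 5 CPM, 2 added to each count, the counting interval wholly beyond 2-fold, a 1.5-fold threshold and protein-coding genes only. After the data were seen, the sum over transcript rows and removal of the length trend by a lowess curve (span 0.3) were added. Alternatives for the overlap of KO and rescue differences were also added then. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used, and plots were drawn with matplotlib 3.10.9.

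The steps were tested on simulated data for KO against WT over 13382 genes, with 200 genes altered. A ratio of 2-fold or more was called for 98% of 50 genes made 3-fold higher, 96% of 50 made 3-fold lower and 0.334% of 13182 unaltered genes. The counting interval held the true ratio for 86% of the 50 genes made 3-fold higher. A larger draw, added for that reason with all 13382 genes made 3-fold higher, gave 95.5%. Of 100 randomly drawn lists of 25 genes, 8% had a percentile outside 2.5 to 97.5 for KO against WT. With 1000 such lists, added for the same reason, the share was 3.9% for KO against WT, 4.2% for rescue against KO and 4.8% for rescue against WT.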

Results

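Gene expression was measured in differentiated C2C12 cells, wild-type or labelled as a knockout of Drp1, the GTPase that divides mitochondria. The series title names muscle fibre type and metabolic pathways as its subject. The comparisons asked how the KO library differed from WT, and which differences were smaller or absent in the library labelled as KO cells expressing FLAG-Drp1. The 3 libraries, 1 per group, were of similar depth, with 13894114 gene counts in WT, 13790417 in KO and 13925296 in rescue. No difference below has a replicate check, so each statement describes these libraries and not the conditions in general. Intervals given with log2 ratios are 95% counting intervals.

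Dnm1l, the gene of Drp1, was still well expressed in the library labelled KO. It had 1823 counts in WT, 1284 in KO and 1481 in rescue. KO was 1.40-fold below WT (log2 ratio -0.48, interval -0.58 to -0.38) and rescue was 1.16-fold above KO (log2 ratio 0.21, interval 0.10 to 0.32) and 1.21-fold below WT (log2 ratio -0.27, interval -0.37 to -0.17). How the knockout was made is not given in the sources used here, and a frameshift can leave the RNA in place, so the RNA level does not decide whether the KO label holds. The small difference in total counts between rescue and KO does not decide the rescue label either. A difference between transcript rows of Dnm1l is given among the results flagged below.

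In KO against WT, genes of fast fibres were lower, genes of the amino acid stress response and the extracellular matrix were higher, and the myosin genes did not move together. Myh4 and Myh1, the fast IIb and IIx myosin heavy chains, were 13.98-fold and 8.78-fold lower in KO, and Myh8, the neonatal form, was 7.44-fold lower. The slow form Myh7 had 822 counts in WT and 741 in KO, and the embryonic form Myh3 was 1.25-fold higher. Fgf21 and Gdf15, hormones secreted under mitochondrial stress, were 5.49-fold and 2.19-fold higher in KO. Of 13382 genes, 716 were at least 2-fold higher and 545 at least 2-fold lower. The counting interval lay wholly beyond 2-fold for 350 and 271 genes. Without the low-count filter 3331 genes were higher and 3606 lower, so which direction held more genes depended on the filter.

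The fast fibre list had a median log2 ratio of -0.51 in KO against WT (counting interval -0.55 to -0.46), below all 10000 matched random lists. Of its 19 measured members, 5 were at least 2-fold lower and none higher. Besides Myh1 (log2 ratio -3.13, interval -3.28 to -2.99) and Myh4 (-3.78, interval -4.38 to -3.28), these were Pgam2, a muscle glycolytic mutase (3.16-fold lower), Mylk2, skeletal myosin light chain kinase (2.27-fold lower), and Eno3, muscle enolase (2.21-fold lower). Myh2, the IIa myosin, had 373 counts in WT and 371 in KO.

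The slow fibre list had a median of -0.10, at percentile 19.4 (-0.25 without the low-count filter), and its members went both ways. Mybpc1, slow myosin binding protein C, had 223 counts in WT and 2 in KO (log2 ratio -6.46, interval -9.83 to -4.91), and Myh7b was 7.66-fold lower. Ankrd2, a stretch-responsive ankyrin repeat protein, was 6.72-fold higher in KO. The embryonic and neonatal list had a median of -0.05 at percentile 36.7, with Igf2, an insulin-like growth factor, 3.77-fold higher and Myl4 1.67-fold lower.

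Differentiated muscle genes were lower as a list, with a median of -0.32 (interval -0.38 to -0.27), below all 10000 matched lists. Of 42 measured members, 11 were at least 2-fold lower and 1, Cox6a2 (named after its value was seen), higher. Trdn, the triadin of the calcium release complex, was 65.1-fold lower, with 663 counts in WT and 10 in KO. Cav3, muscle caveolin, had 160 counts in WT and 2 in KO (log2 ratio -5.98, interval -9.35 to -4.42). Cox7a1, a muscle cytochrome oxidase subunit, was 5.90-fold lower (log2 ratio -2.49, interval -3.85 to -1.47), Actn2 was 5.58-fold lower and Ckm, muscle creatine kinase, was 3.04-fold lower. Acta1, skeletal actin, was 1.16-fold higher, among the 11 members above 0.

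Myogenic regulators and fusion genes had a median of -0.25 at percentile 1.41 (-0.40 without the low-count filter), with 3 of 14 at least 2-fold lower. These were Mef2c, a transcription factor of muscle differentiation (4.15-fold lower), Cdh15, M-cadherin (3.44-fold lower), and the fusion peptide gene Mymx (2.13-fold lower). Myog, myogenin, was 1.38-fold higher and Myod1 was 1.46-fold lower. Cell cycle genes were also lower, with a median of -0.49 below all 10000 matched lists. Ccne2, Rrm2 and Cdc6 were the 3 of 40 that were at least 2-fold lower. The myoblast list had a median of -0.11 at percentile 13.9, with Heyl, a Notch target, 9.55-fold lower and Sphk1 2.16-fold higher. The myoblast median was 0.0224 without the low-count filter.

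**Figure D1:**
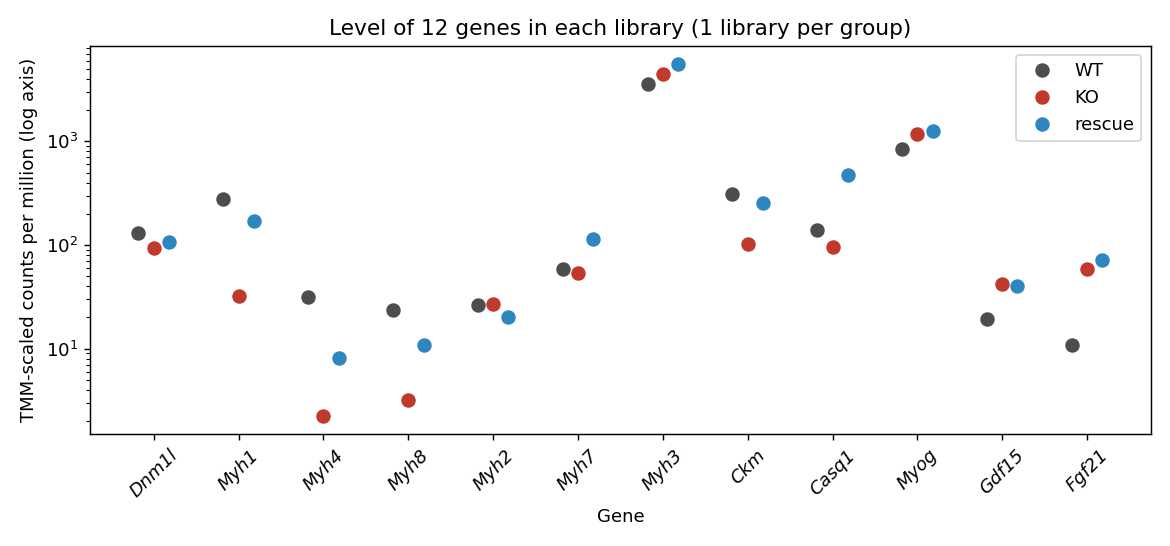
TMM-scaled CPM on a log axis for 12 genes, with 1 point per library for WT, KO and rescue and no error bar because there was 1 library per group. Myh1 had 3941 counts in WT, 441 in KO and 2327 in rescue, while Fgf21 had 151, 815 and 994.

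ATF4 and mitokine genes were higher in KO, with a median of 1.17 (interval 1.06 to 1.25) above all 10000 matched lists. Of 34 measured members, 19 were at least 2-fold higher and none lower. Cth, which makes cysteine from cystathionine, was 8.01-fold higher and Trib3, a pseudokinase induced by ATF4, was 5.87-fold higher. Aldh1l2, a mitochondrial folate enzyme, was 4.10-fold higher, and the cystine transporter Slc7a11 was 3.44-fold higher. Fgf21 (log2 ratio 2.45, interval 2.21 to 2.72) and Gdf15 (1.13, interval 0.92 to 1.35) belong to this list.

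Extracellular matrix and fibroblast genes had a median of 0.85, above all 10000 matched lists, with 9 of 33 at least 2-fold higher and 2 lower, Dcn and S100a4, both named after their values were seen. Postn, periostin, was 9.05-fold higher, with 1120 counts in WT and 9959 in KO. The collagen VI genes Col6a2 and Col6a1 were 6.91-fold and 5.58-fold higher, and Col1a1 was 3.64-fold higher. Sterol and fatty acid synthesis genes were lower, with a median of -0.63 below all 10000 matched lists. Of 27 measured, 3 were at least 2-fold lower, among them Idi1 (2.15-fold) and Fdps (2.03-fold), which act in isoprenoid synthesis.

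Respiratory chain genes were lower in KO by small amounts. Complex I genes had a median of -0.28 (interval -0.32 to -0.23) and complex II to V genes a median of -0.30 (interval -0.34 to -0.26), both below all 10000 lists matched on expression. None of the 36 and 42 members reached 2-fold. Ndufb2 and Ndufs4 of complex I were 1.65-fold and 1.45-fold lower, and Atp5k of ATP synthase and Cox7b of complex IV were 1.99-fold and 1.83-fold lower. Glycolysis genes had a median of -0.32 below all 10000 lists. Eno3 and Pgam2, the 2 of 26 measured members at least 2-fold lower, also belong to the fast fibre list and are no separate result here. Pfkfb3, which makes the activator of phosphofructokinase, was 2.16-fold higher.

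The KO library also differed from the others by transcript length, and the complex I and complex II to V lists hold short transcripts (median lengths of 922 and 828 bases, beside 2887 for the fast fibre list). Among 10283 protein-coding genes with 100 or more counts, the decile of shortest transcripts (1029 genes, median length 994 bases) had a median log2 ratio of -0.21 in KO against WT and 0.23 in rescue against KO. The decile of longest transcripts (1029 genes, median length 9976 bases) had 0.20 and -0.20. Among lists matched on length too, the KO against WT median lay at percentile 2.05 for complex I, 0.24 for complex II to V, 0.03 for glycolysis and 0 for fast fibre and differentiated muscle genes. With the length trend removed, an alternative added after the data were seen, the complex I median was -0.16 and that of complex II to V was -0.19.

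**Figure D2:**
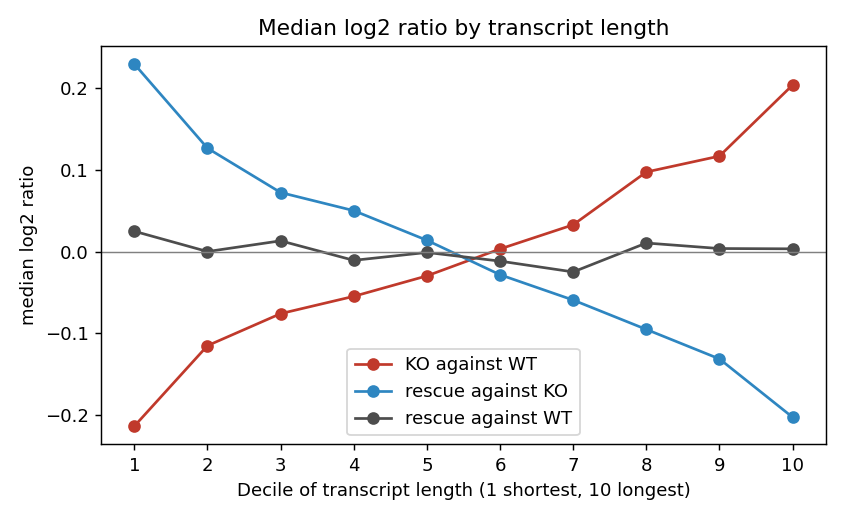
Median log2 ratio of each pair of libraries (vertical axis) in deciles of protein-coding genes ordered by transcript length (horizontal axis, 1 shortest and 10 longest). KO against WT goes from -0.21 to 0.20 and rescue against KO from 0.23 to -0.20, while rescue against WT lies between -0.0248 and 0.0249.

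Other mitochondrial lists lay near 0 in KO against WT. The citric acid cycle list was at percentile 48.2, with Mdh2 1.39-fold lower, and fatty acid oxidation genes were at percentile 45.8. Within the latter, Fabp3, a muscle fatty acid binding protein, was 5.27-fold lower, while Acot2, a mitochondrial thioesterase, and Lpl were 4.73-fold and 3.84-fold higher. Mitochondrial biogenesis genes were at percentile 71.4, and Ppargc1a, the coactivator PGC-1alpha, had 80 counts in WT and 45 in KO. In the fission and fusion list none of 21 members reached 2-fold. Its median was 0.08 at percentile 72.6 (-0.0844 with the length trend removed), and Fis1, a fission adaptor, was 1.71-fold lower.

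The lowest ratios belonged to genes nearly undetected in KO. Ppp1r14c, a phosphatase inhibitor, had 349 counts in WT and 0 in KO (at least 114-fold lower), and Magea13 had 267 and 0 (at least 87.4-fold lower). Gprc5c had 498 and 1 (log2 ratio -8.35, interval -14.24 to -6.45), Pdgfd, a growth factor, had 416 and 2 (-7.35, interval -10.73 to -5.81), and Cd55 had 238 and 1 (-7.29, interval -13.18 to -5.38). Myo18b, an unconventional myosin of muscle, was 56.4-fold lower and Ctrb1 was 21.0-fold lower. The highest was Kcnj15, a potassium channel, with 4 counts in WT and 239 in KO (60.8-fold). Gprin3, Mme (the protease neprilysin), Hsd11b1 (which regenerates glucocorticoid) and Col28a1 were 28.4-fold, 27.2-fold, 23.7-fold and 20.5-fold higher.

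In rescue against KO, muscle and fast fibre genes were higher as lists. No measured member of the ATF4 and mitokine list or of the matrix list differed 2-fold from KO, and both were slightly lower as lists. Myh1 was 5.29-fold higher in rescue than in KO (log2 ratio 2.40, interval 2.25 to 2.55), Myh4 3.59-fold and Myh8 3.42-fold, while Myh2 was 1.33-fold lower (log2 ratio -0.41, interval -0.64 to -0.18). Casq1, the calcium store protein of fast fibres, was 4.97-fold higher, with 1318 counts in KO and 6534 in rescue, above the 1972 of WT. Fgf21 and Gdf15 had 994 and 549 counts in rescue beside 815 and 582 in KO. At least 2-fold higher were 174 genes and at least 2-fold lower 77. The counting interval lay wholly beyond 2-fold for 41 and 5 genes, the latter being Gm6710, Gm5611, Entpd4b, H2-T-ps and Gm7030, named after their values were seen.

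Fast fibre genes had a median of 0.63 in rescue against KO (interval 0.60 to 0.71), with 5 of 19 at least 2-fold higher (Mybpc2 besides Myh1, Myh4, Casq1 and Pgam2), and differentiated muscle genes a median of 0.42 (interval 0.38 to 0.47), with 10 of 42. Both lay above all 10000 random lists, also when matched on length. Tcap, the titin cap protein, was 6.18-fold higher, Cox7a1 6.14-fold, Pgam2 3.43-fold and Ckm 2.48-fold. Cav3 had 2 counts in KO and 4 in rescue, 39.2-fold below WT, and Trdn had 10 and 37. Slow fibre genes had a median of 0.51, above all 10000 lists, with 4 of 14 at least 2-fold higher. These were Mybpc1 (2 counts in KO and 27 in rescue, log2 ratio 3.46, interval 1.77 to 6.88), Myh7b (3.14-fold), Myl2 (2.71-fold) and Myh7 (2.14-fold, log2 ratio 1.10, interval 0.97 to 1.23). The embryonic and neonatal list had a median of 0.32, and Acta1 was 1.24-fold higher.

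Beyond these lists, the highest genes in rescue against KO included Padi2, a protein deiminase (5.28-fold), Nmrk2, a muscle nicotinamide riboside kinase (4.07-fold), Popdc2 (3.76-fold), Bc1, a short noncoding RNA (3.30-fold), Hspb7 (3.14-fold) and Pgm5 (3.05-fold). Fabp3 was 3.67-fold higher, and Colq, the collagen tail of acetylcholinesterase, was 5.58-fold higher. Complex I and complex II to V genes had medians of 0.30 and 0.31, above all 10000 lists matched on expression and on length. With the length trend removed these medians were 0.12 and 0.10. Ribosomal protein genes had a median of 0.20 at percentile 99.99 by expression and 58.7 by length as well, and it was -0.0121 with the trend removed. Glycolysis genes had a median of 0.15 at percentile 99.7. Sterol and fatty acid synthesis genes had a median of 0.13 at percentile 99.66, and myogenic regulators and fusion genes one of 0.18 at percentile 99.45.

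The ATF4 and mitokine list had a median of -0.08 in rescue against KO (interval -0.12 to -0.04), at percentile 2.16, or 0.02 by length as well. Of its 34 members 24 lay below 0 and 10 above, and none reached 2-fold. Aldh1l2 was 1.34-fold and Slc7a11 1.42-fold below KO. The extracellular matrix list, of long transcripts (median length 4897 bases), had a median of -0.21 at percentile 0 (-0.12 with the length trend removed), with Col6a1 1.45-fold and Fbn1, fibrillin 1, 1.41-fold lower and Postn 1.06-fold higher. Among genes with a named symbol and at least 200 counts in the higher library, the lowest ratios were those of Mir6236 1.85-fold, Zbed6 1.70-fold, Trim56 1.68-fold and Mme 1.66-fold below KO. Mir6236 belongs to the loci of structural RNA or matching ribosomal RNA that are described at the end. Myoblast genes had a median of -0.19 at percentile 0.17, with Notch3 1.41-fold lower.

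Against WT, the rescue library kept the stress, matrix, sterol and cell cycle differences and had fast fibre and respiratory chain medians near WT, with fast fibre members going both ways. There were 614 genes at least 2-fold higher and 411 at least 2-fold lower, with the counting interval wholly beyond 2-fold for 293 and 187. The ATF4 list had a median of 1.03 with 18 of 34 members at least 2-fold higher, the matrix list 0.58, the sterol list -0.61 and the cell cycle list -0.48. Myogenic regulators and fusion genes also stayed below WT, with a median of -0.25 at percentile 0.46. Myoblast genes had a median of -0.38 at percentile 0, further from WT than the -0.11 of KO. Fast fibre, complex I and complex II to V genes had medians of 0.12, 0.05 and -0.06, at percentiles 84.2, 82.3 and 10.3. Slow fibre genes lay above WT with a median of 0.54, above all 10000 lists, with Ankrd2 (log2 ratio 2.80) and Myl2 (1.39) at least 2-fold higher. Of the 14 members 5 lay below WT, and Mybpc1 and Myh7b were 8.10-fold and 2.44-fold lower. Of the fast fibre genes, Myh4 and Myh1 were 3.90-fold and 1.66-fold below WT and Casq1 was 3.38-fold above.

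**Figure D3:**
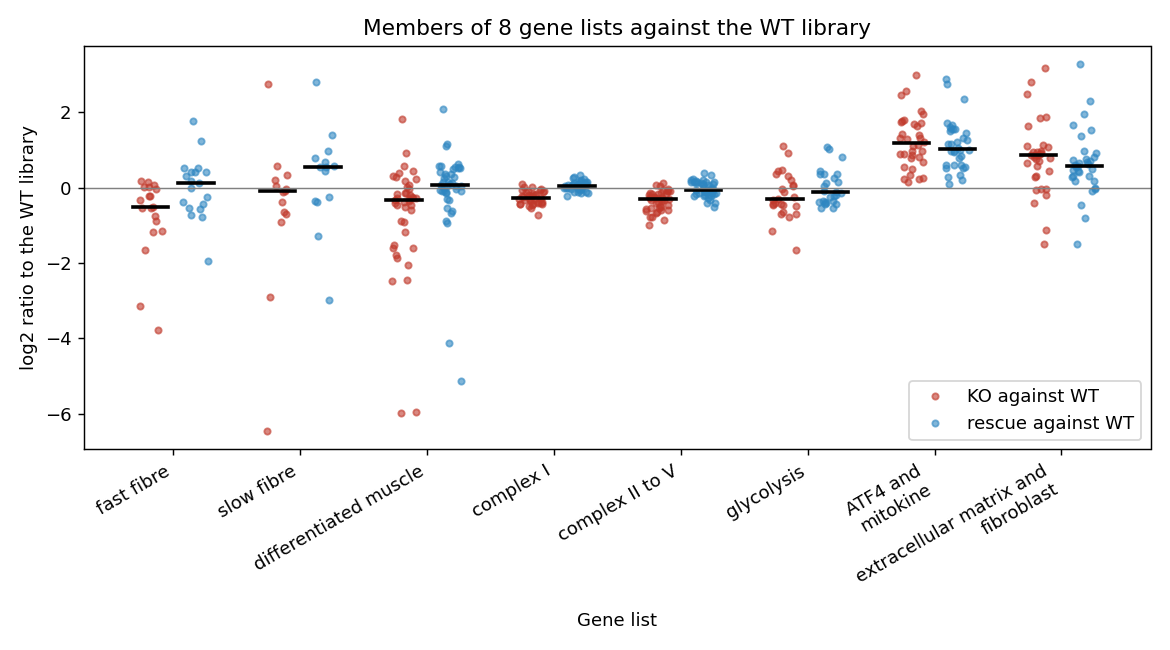
Log2 ratio to the WT library (vertical axis) of each measured member of 8 gene lists (horizontal axis), with KO in red, rescue in blue and the list median as a black bar. The fast fibre median is -0.51 in KO and 0.12 in rescue, while the ATF4 and mitokine median is 1.17 and 1.03.

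Of the 1261 genes at least 2-fold different in KO against WT, 189 (15.0%) lay nearer WT than KO in rescue, and 801 (63.5%) were still at least 2-fold different from WT the same way. The share nearer WT was 25.1% among the 545 genes lower in KO and 7.26% among the 716 higher. Among the 621 genes whose counting interval for KO against WT lay beyond 2-fold, 9.98% lay nearer WT and 85.2% were still 2-fold different. Both counting intervals lay beyond 2-fold the same way for 401 genes. In 141 genes the rescue library was at least 2-fold the opposite way from KO, 111 of them lower in KO. The 10 clearest were Myh1, Myh4, Myh8, Mybpc1, Trdn, Popdc2, Nmrk2, Tcap, Fabp3 and the synaptic gene Nrxn3 (207 counts in WT, 27 in KO and 114 in rescue). Some of them still lay at least 2-fold below WT in rescue, namely Trdn (17.6-fold), Mybpc1 (8.10-fold), Myh4 (3.90-fold) and Myh8 (2.18-fold). Trdn, Ppp1r14c, Magea13, Gprc5c, Pdgfd, Cd55, Myo18b, Hsd11b1 and Kcnj15 were among the clearest that stayed 2-fold from WT. Ppp1r14c had 0 counts in rescue and Hsd11b1 had 32, 746 and 684.

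Because the comparisons share libraries, some of this arises with no effect. Simulated libraries with no effect put 53.02% of 2-fold genes nearer WT and kept 17.8% at 2-fold, as means of 100 Poisson draws. Those shares rest on a mean of 45.8 genes per draw that reached 2-fold by counting noise, against 1261 observed. They are therefore no baseline for the observed shares. The 801 genes 2-fold from WT the same way in KO and rescue compare with a simulated mean of 8.17, or 80.8 at an assumed coefficient of variation of 0.2. Independent lists of these sizes would share 49.6. The 141 genes that went opposite ways compare with a simulated mean of 10.01, or 82.4 (highest draw 105) at the assumed coefficient of 0.2, and with 11.2 for independent lists. The ratios of KO to WT and of rescue to KO had a covariance of -0.116 across genes (simulated -0.0194, or -0.105 at 0.2) and a correlation of -0.447 (simulated -0.502). Across genes, which are not independent replicates, the log2 ratios of KO and of rescue to WT had a correlation of 0.89 (simulated 0.49) and a covariance of 0.455 (simulated 0.0189, a difference of 0.436, or 0.105 at the assumed coefficient of 0.2). With 1 WT library the controls could not be split, and part of the excess may come from that shared library.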

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

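The tests on neighbouring genes, including the subtraction of regional medians, and the list medians with the length trend removed were chosen only after related values had been seen.

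Reads of Dnm1l that fell on 1 annotated transcript but not on another numbered 1 in WT, 1 in KO and 80 in rescue. No comparison above uses this difference itself. The row behind the Dnm1l gene count had the same counts as the first transcript, so its 1481 counts in rescue appear to include these reads. The other transcript had 1283 counts in KO and 1401 in rescue, a smaller gap than in the gene count. The rescue value stands above both other libraries. This pair of transcripts was picked from 25 Dnm1l rows after the data were seen. In this pair, Dnm1l reads of the rescue library differed from those of KO in more than their total, which bears on the rescue label without deciding it. The source of these reads was not tested.

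Complex I, complex II to V, fast fibre and differentiated muscle genes were lower in KO than in WT and rescue, in a KO library that also ran low in short transcripts. If the transcript length trend of the KO library were the whole cause, lists matched on expression and length would match these medians. Of 4 percentiles for the respiratory lists, 4 lay outside the central 95% of such lists, and so did 4 of 4 for the muscle lists. Each set covers KO against WT and rescue against KO, which share the KO library, so its percentiles are not separate results. For the muscle lists they argue against length as the whole cause. For the respiratory lists the 5 length bins were coarse. In rescue against KO the decile of shortest transcripts had a median of 0.23, above the central 95% for either list (up to 0.22). Those percentiles cannot decide. In KO against WT that decile had -0.21, inside the central 95%, so percentiles of 2.05 and 0.24 argue only weakly against length. Removing the trend took complex I from -0.28 to -0.16 in KO against WT and from 0.30 to 0.12 in rescue against KO. A part of the respiratory difference may therefore be the length trend, and an effect of Drp1 stays open and untested with 1 library per group.

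The 801 genes that differed 2-fold from WT the same way in KO and rescue include several near 0 counts in both libraries, such as Ppp1r14c and Cd55. Counting noise of the shared WT library gave at most 16 such genes in 100 draws. The transcript length trend reached decile medians of only -0.21 and 0.20 in KO against WT, too small for a 2-fold difference. In rescue against WT its decile medians lay between -0.0248 and 0.0249. That 97.3% stayed 2-fold from WT in both after its removal therefore adds little. Window medians over 100 neighbouring genes reached only -0.26 and 0.27, too small for a 2-fold difference, so that 97.6% staying 2-fold in KO against WT after subtracting such medians adds little, and dosage of narrower stretches or single genes was not tested. Differences between the WT cells and the cells behind both other libraries that predate or accompany the knockout, a lasting effect of Drp1 loss and incomplete re-expression all may contribute and stay open.

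Neighbouring genes shared their ratios to WT. The SD of medians over windows of 100 neighbouring genes, with transcript length and GC trends removed, was 0.0965 for KO against WT, beyond the highest of 100 shuffles of gene order (0.0480), which argues against those trends. The same SD was 0.0904 for rescue against WT (highest shuffle 0.0425) but 0.0200 for rescue against KO (highest shuffle 0.0212), where without removal of these trends it was 0.0339, above its shuffles (0.0291). With the trends removed, in the window from Hnrnpul2 to Ifit3 the median log2 ratio to WT was 0.27 in KO and 0.27 in rescue, and from Cmpk1 to Clspn it was -0.26 and -0.22. A candidate explanation is a regional difference in gene dosage between the WT cells and the cells behind the KO and rescue libraries. It is a hypothesis found and tested on the same data, and regional differences in chromatin state would look alike. Because both ratios share the WT library, the values cannot tell on which side such a difference lies.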

How the results depend on the processing

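The tests with summed transcript rows, with the length trend removed and of the overlap of KO and rescue differences were chosen only after the data were seen. Of 215 named ratios of 2-fold or more, none changed sign under the scalings, 2 added counts or length removal, and none of 202 did with summed rows. They fell below 2-fold for 6 with 2 added counts, 6 with length removal, 3 with library totals, 2 with summed rows and 1 with DESeq2 size factors. Dnm1l ratios stayed within their counting intervals under each of these settings. Over all results and settings, 3308 single-gene values stayed within their counting interval and 163 left it, and 602 list medians stayed within theirs while 45 left it. Most shifts came from 1 setting. Removal of the length trend gave 152 of those 163 values and 29 of those 45 medians, while 547 values and 63 medians stayed under it. Besides these, 1 called list changed sign. Some other medians, near 0 or of few genes, changed sign as well, within or beyond that interval. Depth limits the weaker genes: without a low-count filter 23623 genes entered, and the larger counts come from genes with few reads. For the other shifts the cause was not tested.

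The numbers of genes at least 2-fold higher and lower were as follows. Without a filter they were 3331 and 3606 (KO against WT), 2862 and 2412 (rescue against KO) and 3431 and 3292 (rescue against WT). At a mean of 5 CPM they were 397 and 244, 54 and 7, and 325 and 163. With the counting interval beyond 2-fold they were 350 and 271, 41 and 5, and 293 and 187. At a 1.5-fold threshold they were 1625 and 1395, 510 and 372, and 1391 and 1070. In rescue against KO, summed rows gave 110 and 48, and protein-coding genes 45 lower. The share nearer WT in rescue was 11.4% at a mean of 5 CPM and 9.98% with the interval beyond 2-fold, where the share still 2-fold was 85.2%. Genes 2-fold from WT in both numbered 405 and 401 under these settings.

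List medians that left their counting interval follow. With library totals they were 0.30 for embryonic genes (rescue against KO), and, in rescue against WT, 0.0212 for complex I, -0.0947 for complex II to V, -0.64 for sterol and 0.00772 for neuromuscular junction genes. Without a filter, KO against WT gave -0.25 for slow fibre genes, -0.40 for myogenic regulators, 0.0224 for myoblast genes, -0.16 for p53 targets and 0.0254 for osteoblast markers. It gave 0.0528 (rescue against KO) and -0.31 (rescue against WT) for myogenic regulators and 0.44 for adipocyte markers (rescue against WT). Myoblast genes had -0.00526 (KO against WT) and -0.28 (rescue against WT) at a mean of 5 CPM, and -0.0146 (KO against WT) with summed rows.

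With the length trend removed, 1 called list changed sign: ribosomal protein genes in rescue against KO, at -0.0121, with 0.14 in KO against WT and 0.18 in rescue against WT. In KO against WT the other medians were -0.0844 (fission and fusion), -0.38 (fast fibre), -0.35 (myogenic regulators), -0.39 (differentiated muscle), -0.21 (myoblast), -0.16 (complex I), -0.19 (complex II to V), 0.0205 (fatty acid oxidation), 0.00515 (Akt and mTOR), -0.74 (sterol), -0.00596 (neuromuscular junction), 0.00727 (p53), 0.73 (matrix) and 0.39 (osteoblast). In rescue against KO they were 0.51 (fast fibre), 0.42 (slow fibre), 0.29 (embryonic), 0.51 (differentiated muscle), 0.12 (complex I), 0.10 (complex II to V), 0.0539 (fatty acid oxidation), -0.0188 (chaperone and protease), -0.00141 (Akt and mTOR), 0.15 (sterol), 0.0505 (neuromuscular junction) and -0.12 (matrix). Complex I had 0.00746 in rescue against WT.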

Other observations

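Several gene groups outside muscle structure also differed. Interferon response genes had a median log2 ratio of 0.48 in KO against WT, above all 10000 matched lists, with 4 of 27 at least 2-fold higher and none lower. Ifi44, an interferon-induced gene, was 5.67-fold higher, the immunoproteasome subunit gene Psmb8 4.10-fold, the RNA sensor Ifih1 2.40-fold and Ifit3 2.08-fold. Their median in rescue against WT was 0.38. Cytokine genes had a median of 0.32 at percentile 99.1, with 5 of 17 at least 2-fold higher and 3 lower. Besides the genes with values here, these were Cxcl5, Ptgs2 and Il1rn, and also Ccl5 and Lif, the latter pair named after their values were seen. Inhba, an activin subunit, was 3.96-fold and the chemokine gene Cxcl12 3.88-fold higher in KO, while Fst, follistatin, which binds activin, was 3.63-fold lower in KO and 2.06-fold higher in rescue than in KO.

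Some lists held members with large ratios in both directions or beside a small median. Igf1 had 21 counts in WT, 195 in KO and 165 in rescue (9.45-fold higher in KO), and Rictor was 2.06-fold higher, within an Akt and mTOR list at percentile 85.5 (41.7 by length as well). The metallothionein genes Mt2 and Mt1 were 4.12-fold and 2.94-fold lower and the peroxidase gene Prdx1 2.03-fold lower in KO, within an oxidative stress list at percentile 4.43 (14.7 by length as well), while Sesn2 was 2.44-fold higher. FoxO and atrophy genes had a median of 0.34 at percentile 99.7, with Irs2 2.54-fold higher and Sesn3 2.75-fold lower (28 counts in WT and 10 in KO). Of the neuromuscular junction genes (percentile 35.2), Colq was 9.97-fold lower and Agrn, agrin, 2.61-fold higher in KO.

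Mitochondrial chaperone and protease genes were at percentile 51.3 in KO against WT, with Lonp1, the matrix protease, 1.89-fold higher. Endoplasmic reticulum stress genes were at percentile 80.2, autophagy and mitophagy genes at 12.03, and p53 targets at 14.2. Ribosomal protein genes were at percentile 82.3 by expression and 99.1 by length as well, with a median of 0.05, or 0.14 with the length trend removed. Markers of other cell types were few: 6 of 12 adipocyte markers (percentile 40.3), 3 of 12 osteoblast and cartilage markers (88.8) and 5 of 21 immune, endothelial, epithelial and neural markers (89.6) were measured. The last of these lists had a median of 0.51, with the macrophage marker Cd68 2.54-fold and the endothelial marker Vwf 2.35-fold higher and the neuronal tubulin gene Tubb3 2.29-fold lower in KO. Cd68 had 22 counts in WT and 55 in KO, and Vwf 13 and 30. The adipocyte marker Cebpa was 4.11-fold higher.

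Chosen after their values were seen, several loci of structural RNA or matching ribosomal RNA were higher in KO. LOC118568312 had 92273 counts in WT, 188507 in KO and 147607 in rescue, Lars2 had 15546, 32344 and 23396, and Rpph1, the RNA of ribonuclease P, had 93, 261 and 189. Mir6236 had 345, 911 and 491. Others looked at differed less, with mt-Rnr1 1.53-fold, Rn7sk 1.35-fold and mt-Rnr2 1.05-fold higher in KO. Of these, mt-Rnr1 and mt-Rnr2 were higher in rescue than in KO. All these loci also lay above WT in rescue, with Rpph1 2.07-fold, LOC118568312 1.63-fold and mt-Rnr2 1.22-fold higher. They therefore differ from the length trend, which was near 0 in rescue against WT. The KO library thus differed from WT in such loci as well as by transcript length, and what this means for its other differences was not tested.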
